A study of Homo sapiens with 6 samples.

How the data were processed

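Gene expression was measured by single-read sequencing of poly(A) RNA from human Tregs, with a directional library kit, per the labels' protocols. The 6 libraries were grouped by the treatment in the labels, as 3 vehicle libraries and 3 TCDCA libraries. The aligner, the read counter, the annotation, the use of strand in counting and the genome build are not given in the sources used here.

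One deposited table was used, with 1 gene per line, Entrez Gene identifiers, and 1 value per library. The authors' per-library values were read as RPKM. The unit is inferred from the values and is not named per the file headers: multiplied by a length per gene and a factor per library, they return the deposited group means. The authors' mean columns hold a normalized read signal, the mean over libraries of reads divided by a size factor, per the file headers and the values. The authors' deposited fold column is the ratio of TCDCA to vehicle, and their deposited log2 column is its log2 fold change. The authors' deposited p-value columns hold the p-value of their test and its adjusted form, which equals the Benjamini-Hochberg adjustment over 15541 genes. The table holds the 235 genes with an adjusted p under 0.1, so genes that missed this threshold were not analysed here, and values of some listed genes are not reported here. Of the 235 identifiers, 234 matched RefSeq; 1 symbol that a spreadsheet had turned into a formula was restored from its identifier as ARRDC3. By RefSeq type, 215 were protein coding and 11 lncRNA.

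Whole reads were recovered by solving for the library factors and gene lengths, and 100% of the values came out within 0.01 of a whole number. Size factors were 1.70, 0.735 and 0.860 for vehicle replicates 1, 2 and 3, and 0.951, 0.992 and 1.01 for TCDCA replicates 1, 2 and 3. With GENCODE 29 exon lengths of 232 genes for scale, these correspond to implied totals of 3.89e+07, 1.68e+07 and 1.96e+07 reads and of 2.18e+07, 2.29e+07 and 2.31e+07 reads; the totals are approximate because the authors' gene models are not known. Vehicle replicate 1 was the deepest library, so low genes are measured most precisely there. No count model was used, because the deposited per-library values are not counts. A chi-square test of the recovered reads found every pair of libraries within a group to differ by more than read-counting error (chi-square over degrees of freedom 2.87 to 45.9), so none was treated as a library deposited again. Repeat libraries of 1 sample can also differ by more than counting error, so this does not show that the 6 came from separate samples.

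The test was limma 3.58.1 (R 4.3.3) with a trend on log2(RPKM + 1), TCDCA against vehicle, no covariate, and Benjamini-Hochberg adjustment over the 235 genes at 0.1. The design had been written for a table of all tested genes as one of its cases; as the table held called genes, gene set tests against a background of tested genes were not run. Instead, the direction of each list with at least 5 listed members (4 of 24 lists) was compared with that of the remaining listed genes. This used a two-sided Fisher's exact test, adjusted over the 4. It counts genes measured in the same 6 libraries, which are not independent, so its p-values do not measure replication over samples. The 24 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. By this rule the text names the 8 genes with the largest positive and the 8 with the largest negative log2 difference among genes with a symbol that is not a clone-based, LOC, LINC, antisense or pseudogene name, no overlap between the groups and a mean in the higher group at or above the median of the listed genes, 11.8 RPKM. It also names members of the fixed lists that passed, and says whether STAT3 and the S1PR genes were listed. The position of TCDCA replicate 3 is its distance from the vehicle mean as a percentage of the distance between the vehicle mean and the mean of the other TCDCA libraries. The share of higher genes was tested with an exact binomial test.

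Simulated data used the 235 genes and the spread of these libraries. On them, limma called 50% of 100 genes changed by 0.2 on the log2 scale and 90% of 100 genes changed by 0.5. Of these calls, 0 had the wrong sign, and 2 of 35 unchanged genes were called. Most simulated genes were changed, their noise was independent between genes, and the spread was that of genes the authors had called. These rates therefore do not carry over to the 15541 tested genes. Alternatives were the replicate number as a block, quantile normalization, filters on low values (at least 1 RPKM in at least 3 libraries, or a mean level at or above the lower quartile), a pseudocount of 0.1, adjusted p thresholds of 0.05 and 0.01, a log2 fold change of at least 1, and each library left out. Reads divided by size factors, and adjustment over all tested genes, were added after the data were seen. That adjustment used the p-values of the listed genes only and ranked every unlisted gene behind them. Quantile normalization was over the 235 listed genes only, so every library got the same distribution of values over genes selected for change. Genes that share reads with others are uncertain, among them the metallothioneins, XCL2, MTRNR2L2 and MTRNR2L8 (similar to mitochondrial ribosomal RNA), HLA-DQB1, antisense genes, and microRNA and small nucleolar RNA genes in a poly(A) library. Summaries used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.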

Results

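The data were poly(A) RNA-sequencing profiles of human regulatory T cells (Tregs), the CD4 T-cell subset that restrains other immune cells. The cells were sorted from the blood of healthy donors as CD4+CD25+CD127-/low cells. They were kept for 48 h with beads that engage CD3 and CD28, with interleukin 2 (100 U), and with either water (vehicle) or 100 µM taurochenodeoxycholic acid (TCDCA), a taurine-conjugated bile acid. There were 3 vehicle libraries and 3 TCDCA libraries. Their implied totals were 1.68e+07 to 3.89e+07 reads in the vehicle group and 2.18e+07 to 2.31e+07 reads in the TCDCA group. The deposited table holds 235 genes that the authors called at an adjusted p of 0.1, or 1.51% of the 15541 genes that its adjusted p-values imply were tested. Values below are means ± SD in RPKM (reads per kilobase of gene model, scaled to library size) with n = 3 per group. Folds are ratios of these means, and log2 differences are on the log2(RPKM + 1) scale, which understates changes of low genes. Chromosomal positions are left out because the authors' genome build is not given in the sources used here.

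The comparison asked how exposure to a conjugated bile acid changed the transcriptome of activated Tregs, in a study of bile acids, sphingosine 1-phosphate receptors and STAT3. In TCDCA, 20 of 28 genes of the interferon response were listed as lower and 10 of 22 genes of cholesterol synthesis and uptake as higher. Fewer members of the T-helper lists were listed, IL17F, IFNG and IL9 among those that were higher. Of the 235 listed genes, 135 were higher in TCDCA, with a median fold of 1.27, and 100 were lower, by a median of 23.3%. The differences were small: 5 genes were at least 2-fold higher and 8 at least 2-fold lower. IL17F (Entrez Gene 112744), which encodes a cytokine of T-helper 17 cells, rose from 25.8 ± 3.06 to 41.8 ± 5.43 RPKM, a fold of 1.62 (log2 difference 0.67 ± 0.13 SE, limma adjusted p = 0.0064). It had the smallest adjusted p in the authors' deposited table, 1.86e-06, with a log2 fold change of 0.70. MX1 (4599), an interferon-induced antiviral GTPase, fell from 27.2 ± 1.57 to 15.9 ± 5.48 RPKM, which was 41.5% lower (log2 difference -0.78 ± 0.19 SE, limma adjusted p = 0.0121).

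**Figure D1:**
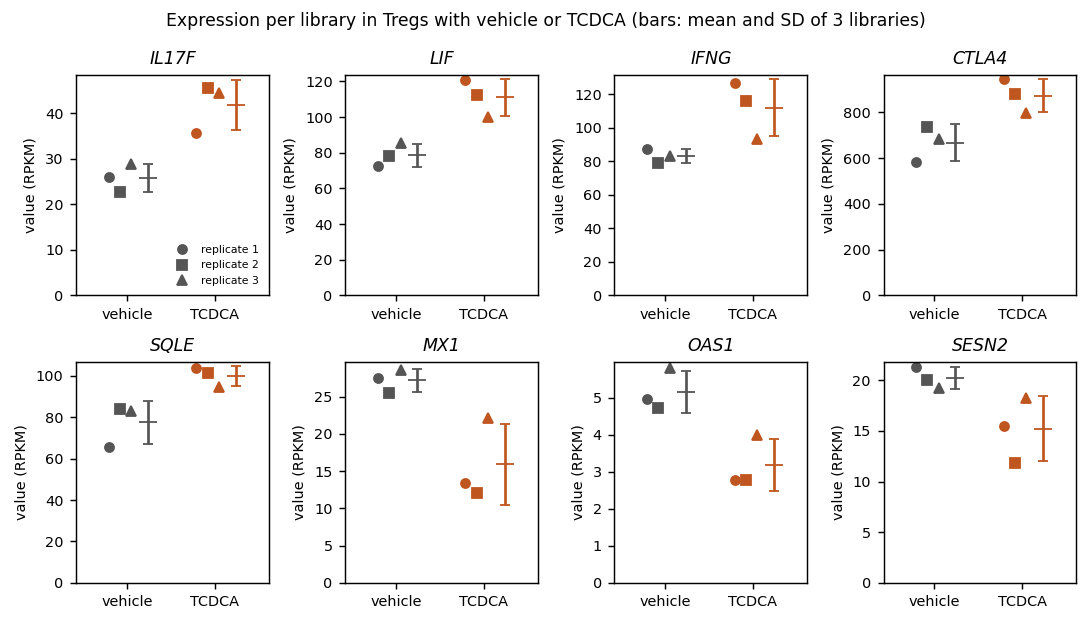
Expression (RPKM, linear axis from 0) of 8 genes in each vehicle (grey) and TCDCA (orange) library, with marker shape for the replicate number and bars for the mean and SD of 3 libraries. IL17F, LIF, IFNG, CTLA4 and SQLE were higher and MX1, OAS1 and SESN2 lower in all 3 TCDCA libraries than in any vehicle library; after quantile normalization the CTLA4 difference was 0.00.

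Genes of the interferon response made up the largest group of a single direction among the fixed lists. Of the 28 members of this list, 20 were in the table and all 20 fell, by a median of 33.5%, while 0 rose. IFIT2 (3433), an interferon-induced protein that binds viral RNA, fell from 5.56 ± 0.676 to 2.69 ± 0.933 RPKM (51.5% lower, limma adjusted p = 0.0064). OAS1 (4938), an enzyme that activates RNase L, fell from 5.16 ± 0.565 to 3.18 ± 0.708 RPKM (38.4% lower, limma adjusted p = 0.00975). ISG15 (9636), a ubiquitin-like modifier, fell by 29.2%, from 26.1 ± 4.38 to 18.5 ± 2.54 RPKM. XAF1 (54739) was 35.1% lower, IRF7 (3665), a transcription factor that drives type I interferon genes, was 33.2% lower, and OAS3 (4940) was 22.8% lower, with a limma adjusted p of 0.1005 without TCDCA replicate 1. The listed members were lower more often than the remaining listed genes, of which 135 were higher and 80 lower. The two-sided Fisher's exact test, over genes that are not independent, gave p = 4.54e-08 adjusted over the 4 lists tested. The groups overlapped in OAS2. All 20 passed limma over the 235 genes. Adjusted over the list alone they had to pass as well, because the largest unadjusted limma p of the 235 genes was 0.0766. The same holds for each list below. TCDCA replicate 3 lay at a median of 37.3% of the way from the vehicle mean to the mean of the other TCDCA libraries in these genes, and 15 of the 20 passed without TCDCA replicate 1 or without TCDCA replicate 2.

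Listed cytokine genes of several T-helper lineages rose. The T-helper 17 list had 4 of 17 members in the table, and all 4 rose: IL17F, CCR6, CSF2 and CCL20. CCR6 (1235), the receptor for CCL20, rose from 12.2 ± 1.49 to 16.7 ± 2.15 RPKM (fold 1.37, limma adjusted p = 0.0233). CSF2 (1437), which encodes GM-CSF, rose from 36.9 ± 4.45 to 49.5 ± 2.81 RPKM (fold 1.34, limma adjusted p = 0.0198). The T-helper 2 list had 3 of 12 members, IL9, IL13 and IL24, and all 3 rose. IL9 (3578) rose from 13.5 ± 0.677 to 21.2 ± 6.01 RPKM (fold 1.57), IL13 (3596) by a fold of 1.51 and IL24 (11009) by a fold of 1.39. In the T-helper 1 list, 4 of 16 members were in the table, of which 3 rose. IFNG (3458), which encodes interferon gamma, rose from 83.2 ± 4.18 to 112 ± 17.2 RPKM (fold 1.35, limma adjusted p = 0.0233), and TNF and IL18R1 rose by folds of 1.38 and 1.21. The counts of these 3 lists were the same adjusted over the list alone, as they had to be. Each list had too few listed members for the test of direction. The groups overlapped in CCL20, IL13 and TNF. TCDCA replicate 3 lay at 56.5% of the way from vehicle in the T-helper 17 genes, 30.9% in the T-helper 1 genes and 7.65% in the T-helper 2 genes. Without TCDCA replicate 1, CCL20, IL13 and TNF had limma adjusted p-values of 0.103, 0.106 and 0.105; IL18R1 had 0.123 there, and 0.111 without TCDCA replicate 2.

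Members of the STAT3 list, which the title of the study concerns, were mostly outside the table. LIF and BCL2L1 were listed of its 20 members, and both rose. LIF (3976), a cytokine of the interleukin 6 family, rose from 78.7 ± 6.51 to 111 ± 10.3 RPKM (fold 1.41, log2 difference 0.49 ± 0.11 SE, limma adjusted p = 0.00975). BCL2L1 (598), an inhibitor of apoptosis, rose by a fold of 1.27, with groups that overlapped. Its value in TCDCA replicate 3, 27.555 RPKM, was below the vehicle mean of 27.605 RPKM. The limma adjusted p of BCL2L1 was 0.15 without TCDCA replicate 1 and 0.165 without TCDCA replicate 2. It was 0.1004 without vehicle replicate 2 and 0.12 without vehicle replicate 3. STAT3, SOCS3 and the receptor genes S1PR1, S1PR2, S1PR3, S1PR4 and S1PR5 were not listed. The 16 genes of sphingosine 1-phosphate signalling and the 19 bile acid receptors and transporters, GPBAR1 and NR1H4 among them, had 0 listed members. A gene that is not listed either missed the authors' threshold or was not tested, and its level was not analysed here.

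A group of 6 receptor genes of activated Tregs rose in TCDCA. Of 23 genes of Treg identity, 7 were in the table. CTLA4, ICOS, TNFRSF9, TNFRSF18, TNFRSF4 and CCR8 rose, and HPGD, which encodes a prostaglandin-degrading enzyme, fell by 19.0% (limma adjusted p = 0.0331, and 0.106 without TCDCA replicate 1 and 0.123 without TCDCA replicate 2). CTLA4 (1493), an inhibitory receptor, rose from 668 ± 79.6 to 874 ± 73.4 RPKM (fold 1.31, limma adjusted p = 0.0211); after quantile normalization its difference was 0.00, as it held the same rank in every library. ICOS (29851) rose from 262 ± 31.9 to 328 ± 13.4 RPKM (fold 1.25, limma adjusted p = 0.0258) and TNFRSF9 (3604) from 103 ± 9.90 to 130 ± 6.32 RPKM (fold 1.26, limma adjusted p = 0.0249). The list did not differ in direction from the remaining listed genes (two-sided Fisher's exact test, adjusted p = 0.244). All 7 also passed limma adjusted over the list alone, as they had to. TCDCA replicate 3 lay at 53.2% of the way from vehicle. Of the 6 genes that rose, 3 passed without TCDCA replicate 1, and 3 after quantile normalization. That normalization was over the listed genes only, so the lost calls cannot tell a shared rise from a difference in scale. FOXP3, the lineage transcription factor of Tregs, was not listed, and the 13 Treg effector molecules, IL10 among them, had 0 listed members.

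Listed genes of cholesterol synthesis and uptake were higher. Of 22 members, 10 were in the table and all 10 rose, by a median fold of 1.27. Against the remaining listed genes, the two-sided Fisher's exact test gave an adjusted p = 0.0115, over genes that are not independent. DHCR7 (1717), which makes cholesterol from its last precursor, rose from 57.7 ± 7.77 to 77.3 ± 9.51 RPKM (fold 1.34, limma adjusted p = 0.0258). SQLE (6713), the squalene epoxidase, rose from 77.6 ± 10.4 to 100.1 ± 4.74 RPKM (fold 1.29, limma adjusted p = 0.0249). SCD (6319), a fatty acid desaturase and 1 of 2 listed members of the 11 liver X receptor targets, rose from 104 ± 13.0 to 145 ± 23.3 RPKM (fold 1.40). The other, FASN (2194), rose by a fold of 1.28 and had limma adjusted p-values of 0.104 without TCDCA replicate 1 and 0.109 without TCDCA replicate 2. All listed members of both lists passed limma adjusted over the list alone, as they had to. In the cholesterol genes, TCDCA replicate 3 lay at 43.5% of the way from vehicle, and the groups overlapped in INSIG1. Of these genes, 3 passed without TCDCA replicate 1, 6 without TCDCA replicate 2 and 4 after quantile normalization. That normalization was over the listed genes only, so the lost calls cannot tell a shared rise from a difference in scale.

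Listed genes of 2 stress lists were lower. In the integrated stress response, 5 of 20 members were in the table and all 5 fell, by a median of 21.3%: CEBPB, DDIT3, PHGDH, SESN2 and STC2. The two-sided Fisher's exact test gave an adjusted p = 0.0175, over genes that are not independent. CEBPB (1051), a transcription factor, fell from 11.5 ± 0.269 to 8.57 ± 0.833 RPKM (25.3% lower, limma adjusted p = 0.0165). SESN2 (83667), a stress-induced leucine sensor, fell from 20.2 ± 1.07 to 15.2 ± 3.23 RPKM (24.7% lower, limma adjusted p = 0.0308, and 0.12 without TCDCA replicate 2). Without TCDCA replicate 2, 1 of the 5 passed. In the list of oxidative stress genes and metallothioneins, 4 of 19 members were in the table and all 4 fell: FTH1, the ferritin heavy chain, and the metal-binding proteins MT1E, MT1F and MT1G. MT1G (4495) fell from 2.06 ± 0.188 to 0.712 ± 0.375 RPKM, on 3 to 40 recovered reads per library. Metallothionein paralogs are near-identical, so how reads divide among them is uncertain. FTH1 (2495) was 15.6% lower, with limma adjusted p-values of 0.13 without TCDCA replicate 1 and 0.111 without TCDCA replicate 2. Both lists kept these counts adjusted over the list alone, as they had to. TCDCA replicate 3 lay at 57.3% of the way from vehicle in the integrated stress response genes and 68.5% in the oxidative stress genes. The 16 genes of the unfolded protein response and 15 heat-shock genes had 0 listed members.

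**Figure D2:**
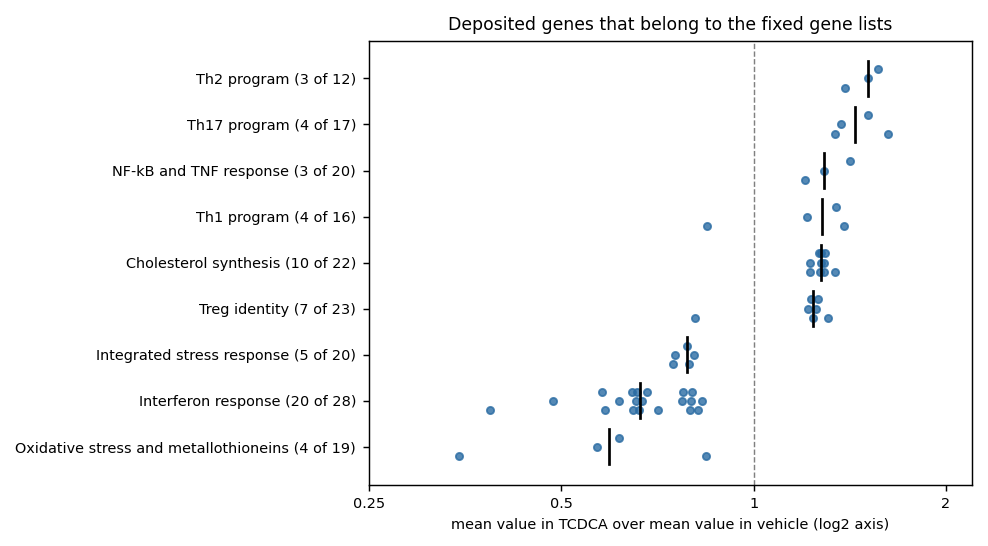
Ratio of the mean RPKM in TCDCA to that in vehicle (log2 axis) for each listed member of 9 fixed gene lists, 1 point per gene, with a black bar at the list's median and the listed and total members in brackets. All 20 interferon response genes lie below 1 and all 10 cholesterol synthesis genes above it; the CTLA4 point in the Treg identity list moved to a difference of 0.00 after quantile normalization.

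Among activation genes, CD83, IER3 and LTA rose of 20 genes of the NF-kB response, and CD40LG and NR4A3 of 22 early activation genes. Adjusted over the list alone the counts were the same, as they had to be. LTA (4049), which encodes lymphotoxin alpha, rose from 60.3 ± 4.91 to 85.5 ± 17.1 RPKM (fold 1.42, limma adjusted p = 0.0249). LTA passed with any library left out. The groups overlapped in IER3 and NR4A3. Without TCDCA replicate 1, the limma adjusted p-values of CD83, IER3, CD40LG and NR4A3 were 0.129, 0.129, 0.112 and 0.164, and without TCDCA replicate 2 those of CD83, IER3 and NR4A3 were 0.15, 0.13 and 0.132. Without vehicle replicate 1 those of CD83 and IER3 were 0.12 and 0.105, that of NR4A3 was 0.124 without vehicle replicate 2, and that of CD83 was 0.107 without vehicle replicate 3. TCDCA replicate 3 lay at 15.3% of the way from vehicle in the NF-kB genes. MIR4292 (100422860), a microRNA gene, rose from 8.27 ± 0.836 to 17.6 ± 2.54 RPKM (fold 2.13, limma adjusted p = 0.00268), and SNORD12 (692057), a small nucleolar RNA gene, from 10.98 ± 1.13 to 19.9 ± 2.34 RPKM (fold 1.81, limma adjusted p = 0.00487). They rest on 9 to 29 and 18 to 44 recovered reads per library, and as short noncoding genes in a poly(A) library their values are uncertain. Other genes with large differences and no overlap between groups were XIRP1 (165904; 7.47 ± 0.681 to 11.97 ± 3.35 RPKM, fold 1.60) and FCER2 (2208), a low-affinity IgE receptor (18.1 ± 1.71 to 26.3 ± 5.34 RPKM, fold 1.45). Among genes that fell, SAMD9L (219285) went from 19.4 ± 1.05 to 12.9 ± 4.004 RPKM, LGALS9 (3965), which encodes galectin 9, from 16.2 ± 1.58 to 12.2 ± 1.40 RPKM, and TXNIP (10628), an inhibitor of thioredoxin, from 62.9 ± 2.26 to 49.6 ± 9.004 RPKM. The limma adjusted p of TXNIP was 0.111 without TCDCA replicate 1 and 0.122 without TCDCA replicate 2. Cell cycle (30 genes), glycolysis and hypoxia (30 genes), and lymphoid homing and quiescence (25 genes) had 0 listed members. So had the markers of B lymphocytes (14 genes), myeloid cells (19 genes) and platelets and erythroid cells (13 genes). Of 18 markers of NK and CD8 T cells, XCL2 (6846) was listed, and it rose from 5.62 ± 0.801 to 9.65 ± 1.07 RPKM (fold 1.72); it has a near-identical paralog, XCL1, so its reads are uncertain.

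All 235 genes passed limma at an adjusted p of 0.1 over the 235 genes, 230 of them at an unadjusted p under 0.05, and 212 of the 235 had groups that did not overlap, where chance gives 10% of genes that were not selected. These genes were selected by the authors on the same 6 libraries, which favours both results. The limma values and the lack of overlap therefore describe them and are not independent evidence. With the adjustment set to 15541 tested genes, 0 passed. The limma p-values of the unlisted genes are not known, and this adjustment ranked all of them behind the listed ones. It therefore gives an upper bound on each adjusted p. Genes that were higher made up 57.4% of the list (exact 95% interval 50.9% to 63.9%, exact two-sided binomial p = 0.0263, over genes that are not independent). Quantile normalization over the listed genes moved their median log2 difference from 0.24 to 0.06. After it, limma called 72 higher and 79 lower genes, so that 47.7% of the calls were higher. Equal distributions over a list of called genes pull the directions towards balance by construction, so this does not test the share of higher genes. TCDCA replicate 3 was the TCDCA library nearest to the vehicle mean in 200 of the 235 genes. Of the 235, 115 passed without TCDCA replicate 1, 131 without TCDCA replicate 2 and 235 without TCDCA replicate 3. The labels do not say that replicates came from separate donors or cultures, so p-values measure the spread between these libraries, which may be technical.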

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

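Adjustment over all tested genes, reads over size factors, and the counts within lists were chosen after the data were seen; the other alternatives were planned. The counts of 135 higher and 100 lower genes stayed within 1.5 times under a pseudocount of 0.1, reads over size factors, a minimum of 1 RPKM in 3 libraries and an adjusted p of 0.05. In limma, quantile normalization left 72 higher and 79 lower genes (47.7% higher). It was over the listed genes only, which pulls the directions towards balance, so it does not test which direction holds the majority. The mean-level filter left 66 lower genes among the fewer tested. An adjusted p of 0.01 left 11 higher and 18 lower, and a log2 difference of at least 1 left 2 and 0. Adjustment over all tested genes left 0 and 0, where 230 had an unadjusted p under 0.05. It ranked the unlisted genes, whose limma p-values are not known, behind all listed ones, so its counts are lower bounds. Leaving out each library gave 53 to 135 higher and 56 to 100 lower genes, the lowest without TCDCA replicate 1 (53 higher) and without TCDCA replicate 2 (56 lower). In the authors' deposited table, an adjusted p of 0.05 keeps 75 higher and 53 lower genes, 0.01 keeps 16 and 17, and a log2 fold change of at least 1 keeps 5 and 8. The share of higher genes was 58.6% (exact binomial p = 0.063), 48.5% and 38.5% under these; the cause was not tested. Within lists, Treg identity had 3 higher genes after quantile normalization and 3 to 6 with a library left out, cholesterol synthesis 4 and 3 to 10, and the integrated stress response 1 to 5 lower genes with a library left out; the cause was not tested. The interferon list kept 15 or more of 20 calls with the block, quantile normalization, a pseudocount of 0.1 or any library left out. At an adjusted p of 0.05 in the authors' deposited table, the Fisher's exact test gave adjusted p-values of 9.46e-07 for the interferon list and 0.0414 for cholesterol synthesis. Both are over genes that are not independent. Treg identity and the integrated stress response had fewer than 5 members left. No list test was possible at a log2 fold change of at least 1, with fewer than 5 members left. Quantile normalization gave 2 genes the opposite sign (NDFIP2 -0.02, ATP13A3 -0.06) and set CTLA4 and MTRNR2L2 to 0. Of 74 genes named by rule or as list members, 30 lost the call without TCDCA replicate 1, 24 without TCDCA replicate 2 and 0 without TCDCA replicate 3, 3, 3 and 4 without vehicle replicates 1, 2 and 3, and 8 with the block; 0 changed sign with a library left out or the block.

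With the replicate number as a block, limma called 107 higher and 83 lower genes. Deviations of same-numbered libraries correlated across genes at -0.34, 0.42 and -0.12, and not every library correlated best with its own number, so the numbers are not taken to pair the samples. Depth limits low genes: MT1G rests on 3 to 40 reads per library.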

Other observations

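The gene sets in this paragraph were put together after the values were seen, and none was tested. Besides the cholesterol genes, 6 genes of fatty acid synthesis, elongation and desaturation were listed (SCD, FASN, FADS1, FADS2, ELOVL6 and HSD17B12). The means of all 6 were higher in TCDCA, with folds of 1.21 to 1.51. The groups overlapped in FADS1, FADS2 and ELOVL6, which had the highest folds. TCDCA replicate 3 lay at a median of 16.4% of the way from vehicle in this set. It was below the vehicle mean in FADS2 (17.1 against 17.4 RPKM) and ELOVL6 (3.39 against 3.42 RPKM). The sterol-related genes TM7SF2, TMEM97 and LRP8 were higher by folds of 1.21 to 1.31, with groups that overlapped in TM7SF2. In all, 14 genes of cytokines and TNF family ligands were listed and all 14 were higher, with folds of 1.26 to 1.83 and a median of 1.41. The highest fold among them, 1.83, was that of CCL1 (6346), a ligand of CCR8, with 18.3 ± 7.45 RPKM in TCDCA (SD, n = 3) and groups that overlapped. CCR8 itself was 1.24-fold higher. Of the cytokine and ligand genes, CCL20, IL13 and TNF also had groups that overlapped, and TCDCA replicate 3 lay at a median of 26.2% of the way from vehicle. A further 11 interferon-inducible genes outside the fixed list were lower, by 17.5% to 48.8%, among them EPSTI1, CMPK2, SAMD9, HERC6 and DHX58. The groups overlapped in HERC6. IFNG was 1.35-fold higher while IRF1 and GBP1, which interferon gamma is known to induce, were 16.9% and 18.2% lower; without TCDCA replicate 1 the limma adjusted p-values of these 2 were 0.129 and 0.149, and without TCDCA replicate 2 they were 0.123 and 0.111. That of GBP1 was 0.102 without vehicle replicate 2. GIMAP4 and GIMAP7, GTPases of lymphocytes, were 20.8% and 21.2% lower. MME (4311), a membrane peptidase, was listed at 0 in each of the 3 TCDCA libraries, with 14, 8 and 12 recovered reads in vehicle replicates 1, 2 and 3. Genes that were higher had a median vehicle level of 13.5 RPKM against 7.38 RPKM for genes that were lower (two-sided permutation test, p = 0.00167, over genes that are not independent).

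All tests in this and the next paragraphs were chosen after the patterns were seen. TCDCA replicate 3 lay between vehicle and the other TCDCA libraries: it was nearest to the vehicle mean in 85.1% of the listed genes, at a median of 49.6% of the way, against 134% for replicates 1 and 2. A single scaling factor by itself is excluded, because the median deviation of TCDCA replicate 3 from the TCDCA mean was -0.12 in genes that were higher and 0.13 in genes that were lower. The genes were selected on these same libraries, so part of these deviations may come from selection. Shallower sequencing is excluded, because the implied total of TCDCA replicate 3 was 1.03 times the mean of the other TCDCA libraries. An admixture of vehicle RNA in 1 fixed share stays open: the position was not shown to differ over 9 fixed lists with 60 listed members (permutation test, p = 0.0745), although list medians ran from 7.65% (T-helper 2) to 68.5% (oxidative stress). No biological explanation was tested, and a weaker response of that culture or donor may also give this pattern.

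Vehicle replicate 1, the deepest library, was lower than the other vehicle libraries in genes that were higher in TCDCA (median deviation from the vehicle mean -0.13) and had a median deviation of -0.00 in genes that were lower. A single scaling factor by itself would give alike deviations in the genes that were higher and those that were lower. Their difference was -0.13 (95% bootstrap interval -0.15 to -0.10, log2, over genes that are not independent). The genes were selected on these same libraries, which favours low values of a vehicle library in genes called higher. A scaling factor together with this selection is therefore not excluded. The makeup of reads outside the table was not analysed here, so a difference in library composition stays open. No biological explanation was tested.

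Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, called all 235 genes in limma, and the highest of the others called 11. The splits are too few for a share under 0.05, and the genes had been selected on the real split.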
